A study of Homo sapiens with 8 samples.

How the data were processed

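Total RNA was isolated from HEK293T and IMR-90 cells with TRIzol, treated with DNase and, for 3 of 4 replicates per line, depleted of rRNA with Ribo-Zero, per the labels' protocols. cDNA was primed with oligo-dT and random hexamers in the presence of actinomycin D, directional libraries were made with a dU second strand cut by UDG, fragments were about 300 bp, and reads were single-end and 100 bp long on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name HTSeq 0.5.3p3, CASAVA 1.8, DESeq and the genome build hg19. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may be shared.

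The 8 deposited count files hold raw counts of reads per Ensembl gene ID for 57659 IDs, with no normalisation by the authors, followed by 5 closing lines that name no gene. Those lines were left out of library sizes and tests. They hold from 63.3% to 75.1% of all counted reads in the 8 libraries, and reads that aligned to more than 1 place are the largest part of them in every library. The authors' deposited table for each line holds a signal per RefSeq transcript with its hg19 position. It was checked by non-negative least squares to be an exact weighted sum of that line's 3 depleted count columns as labelled, with weights of 0.224, 0.211 and 0.763 for HEK293T replicates 1, 2 and 3 and 0.145, 0.539 and 0.462 for IMR-90 replicates 1, 2 and 3. The same table holds an expression score by the authors in 5 steps, 0 for transcripts without signal and 25, 50, 75 or 100 in order of signal over groups of near equal size, which entered no comparison. Gene positions are those of the authors' tables. The reference annotation here is GENCODE v29 on another build, so it gave names and gene types and no coordinates. Names were matched for 47153 IDs from a table of gene IDs, 246 from GENCODE v29 and 426 through RefSeq accessions, and 9834 IDs kept no name.

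Samples were grouped by the cell line and the rRNA removal in their labels, giving 3 depleted libraries and 1 without removal per line. The labels call the 4 samples of a line biological replicates. In 1 case per line the title of the library without removal shares its stem with that of a depleted one, so the material behind them may not be independent, and p-values then measure only the spread between these libraries. Libraries are named throughout by their labels. A binomial interval is exact (Clopper-Pearson, 95%), the floor for a count of 0 is 3 counts, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Over the group kept in a comparison, that floor applies to the summed counts. In normalised CPM the floor of 1 library ran from 0.0409 to 0.204 in depleted libraries and was 0.619 and 2.93 in the IMR-90 and HEK293T libraries without removal.

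Genes were tested with edgeR 4.0.16 (robust quasi-likelihood fit and F-test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, two-sided, threshold 0.05) in R 4.3.3. The SE given with an edgeR log2 fold change is its absolute value divided by the square root of the F statistic. It is thus derived from the test and is not a standard error reported by the fit. The cell line comparison used the 6 depleted libraries, the removal comparison all 8 with cell line as a covariate, and a further fit the interaction of both. Levels in normalised CPM are CPM of the TMM-scaled library over all 8 libraries, and are given as mean ± SD. Gene lists, 34 in number, were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were tested, and again with an estimated correlation. The ratio of the libraries without removal used a pseudocount of 1 CPM. Groups of 3 were compared on single values with an exact permutation test. DESeq2 1.42.0 and limma-voom were run as alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

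The groups, lists, tests, most alternatives and the naming rule were fixed before the data were examined. By that rule the text names, of genes past the threshold with at least 10 normalised CPM in the higher group and no overlap between the groups, the 8 with the largest change in each direction, and of each list at most 3 members per direction by abundance. For removal, the same direction in both lines replaced the second condition. No gene met the rule in the cell line comparison as labelled. The rule was therefore applied to the fit without the 2 depleted libraries whose markers go against their labels, and to a removal fit without those and the HEK293T library without removal. Both fits and their alternatives were added after the data were seen. Genes used to compare labels with profiles (COL1A2, FN1, THY1, LIN28B and MEG3 among them) were looked up for that purpose. Features known only by a clone or an ID, genes on the Y chromosome and 2 X-linked non-coding genes were counted and not named. Of the 8 largest lower genes 1 in the cell line fit, 7 of the 8 in the removal fit as labelled and 8 of the 8 in the removal fit without the 3 libraries had no name.

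Other alternatives were RLE size factors, library size as the only scaling, no filter, a filter of 1 CPM in 3 libraries, removal of the RNA classes that rRNA removal could alter, a test against a log2 fold change of 1, and leaving out each depleted replicate. To set profiles against labels, each doubted library was placed on a scale from 0 at its labelled line to 1 at the other line, over genes past the threshold in the 4 other depleted libraries with an absolute log2 fold change of at least 2 and at least 50 normalised CPM. Libraries were also thinned to equal depth, with 10 draws to 754609 counts for all 8 libraries and 10 draws to 11208901 counts for the depleted ones.

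The code was tested on simulated counts with 200 changed genes. In the labelled design, on 16288 genes at the spread measured with 6 libraries, it recovered 0% of 2-fold, 0% of 4-fold and 0% of 16-fold changes, with 0 false calls. With the spread of the 4-library fit the same 6-library design recovered 25.4%, 86.6% and 100% on 16900 genes, with 23 false calls. The 4-library cell line fit recovered 8.96%, 65.7% and 98.5% on 17141 genes, with 24 false calls. The removal fit recovered 0%, 0% and 13.6% on 16506 genes with 8 libraries and 1 false call, and 0%, 31.3% and 54.5% on 18041 genes with 5 libraries and 12 false calls beside 21 and 36 true ones of 4-fold and 16-fold. The interaction fit recovered 0% of each size on 18149 genes, with 0 false calls.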

Results

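RNA from 2 human cell lines was sequenced to measure gene expression across the genome, ribosomal RNA (rRNA) included. HEK293T is an embryonic kidney line transformed with adenovirus DNA and carrying the SV40 large T antigen. IMR-90 is a fetal lung fibroblast line. Per the labels, each line gave 4 biological replicates, of which 3 went through Ribo-Zero rRNA removal and 1 was left without it, so that rRNA itself could be read. The series title places the work in a study of RNA:DNA hybrids and their relation to transcription. Counts assigned to genes ranged from 11573024 to 33989901 in the 6 depleted libraries and were 20764312 in the IMR-90 library without removal and 5761664 in the HEK293T library without removal. After the named rRNA and the features without a gene name were set aside, the last of these held 754609 counts. Per-library levels are in normalised CPM, with TMM scaling over all 8 libraries.

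The first question the labels pose is which genes differ between the lines. Marker genes did not follow the labels in 3 of the 8 libraries. COL1A2, a fibrillar collagen chain made by fibroblasts (ENSG00000164692, hg19 chromosome 7, 94023873 to 94060544), stood at 6648 and 7016 normalised CPM in the libraries labelled IMR-90 replicates 2 and 3. In the library labelled IMR-90 replicate 1 it stood at 4.26, against 5.06 and 4.98 in those labelled HEK293T replicates 1 and 2. The library labelled HEK293T replicate 3 held 7679, and the library labelled HEK293T without removal held 5547, against 4822 in the library labelled IMR-90 without removal. FN1, the fibronectin gene, and THY1, a fibroblast surface marker, divided the libraries the same way. LIN28B, a fetal RNA-binding protein that blocks let-7 maturation, stood at 27.6 in the library labelled IMR-90 replicate 1. It stood at 27.7 and 34.4 in those labelled HEK293T replicates 1 and 2, and at 0.272 in that labelled HEK293T replicate 3. Without removal it stood at 3.90 (4 counts) in the library labelled HEK293T and 0.413 (2 counts) in that labelled IMR-90. These counts are too few to place the former library by this gene. Across 14915 genes, which are not independent replicates, the Spearman correlation was 0.992 between the libraries labelled IMR-90 replicate 1 and HEK293T replicate 1, and 0.698 between those labelled IMR-90 replicates 1 and 2. It was 0.990 between those labelled HEK293T replicate 3 and IMR-90 replicate 2, and 0.696 between those labelled HEK293T replicates 1 and 3. The library labelled HEK293T without removal correlated at 0.947 with the library labelled IMR-90 without removal and at 0.672 and 0.666 with those labelled HEK293T replicates 1 and 2.

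**Figure D1:**
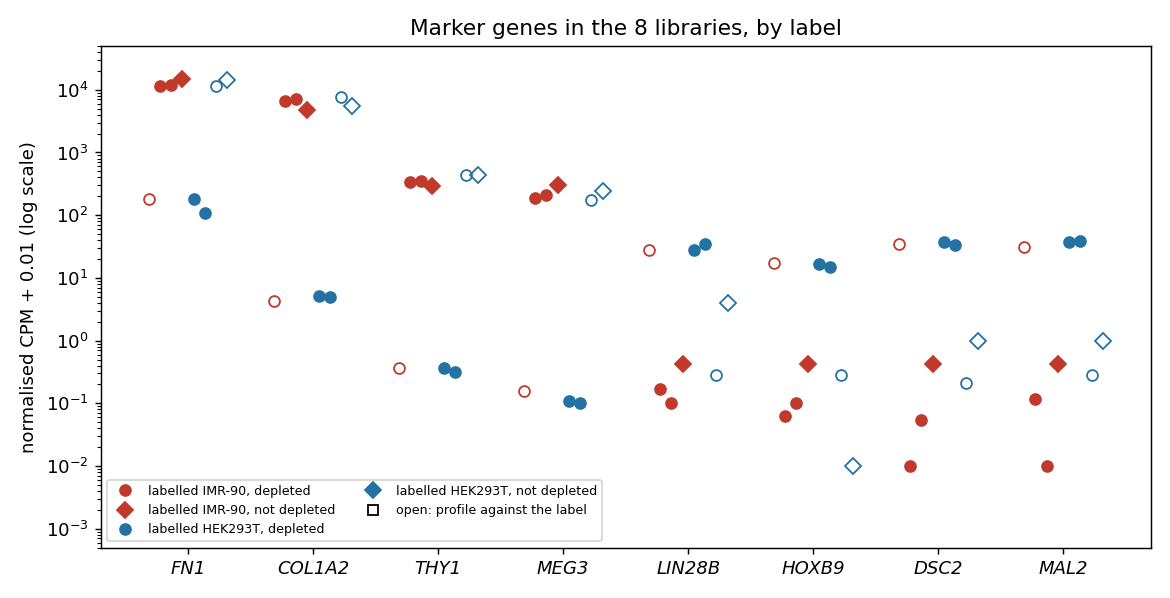
Levels of 8 marker genes in each of the 8 libraries, in normalised CPM plus 0.01 on a log axis, 1 point per library, with color for the labelled cell line and shape for rRNA removal. Open symbols mark the 3 libraries whose points mostly lie with the other line. COL1A2 is an example, at 4.26 in the library labelled IMR-90 replicate 1 and at 7679 in the library labelled HEK293T replicate 3. LIN28B in the library labelled HEK293T without removal lies between the lines, at 3.90 from 4 counts.

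**Figure D2:**
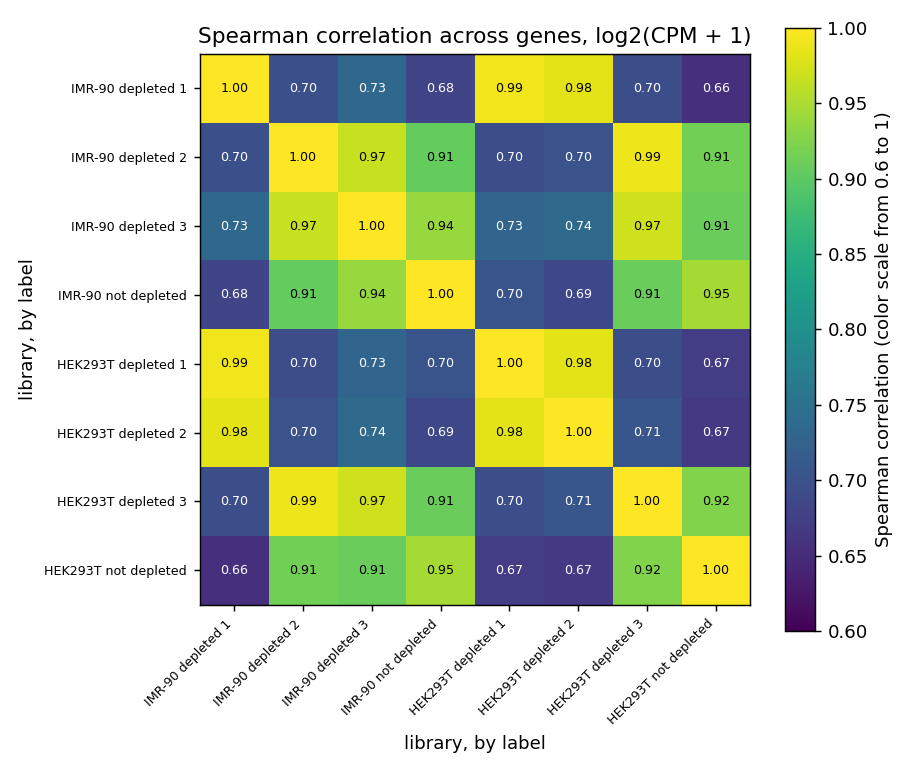
Spearman correlation across 14915 genes, on log2 of CPM plus 1, between each pair of the 8 libraries, with both axes listing the libraries by their labels and the color scale running from 0.6 to 1. The library labelled IMR-90 replicate 1 reached 0.99 with the library labelled HEK293T replicate 1 and 0.70 with the library labelled IMR-90 replicate 2.

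With the 6 depleted libraries grouped as labelled, 3 against 3, no collagen, cell cycle, HOX or imprinted gene differed between the lines at an adjusted p under 0.05, and neither did any other of the 17438 genes tested. edgeR's quasi-likelihood test left 50 genes at an unadjusted p under 0.05. That is far below a share of 0.05 of the genes tested, so it is no sign of a difference. At the adjusted threshold limma-voom called 0 and DESeq2 called 6, all higher in the libraries labelled HEK293T. Of these 6, which lie outside the naming rule and were looked up after their values were seen, 2 were 5.8S rRNA pseudogene copies and 3 were processed pseudogenes of ribosomal protein genes, and 1 is not reported here. They were RNA5-8SP2 (log2 fold change 4.03 ± 0.90, SE, DESeq2 adjusted p = 0.0336), RNA5-8SP5 (4.64 ± 0.95), RPL31P4 (1.22 ± 0.25), RPS24P8 (1.25 ± 0.29) and RPS24P19 (adjusted p = 0.000482), and reads from copies this similar cannot be assigned with certainty. The common biological coefficient of variation was 0.824, and a simulated 16-fold change at that spread was recovered in 0% of cases. At the spread of the fit without the libraries labelled IMR-90 replicate 1 and HEK293T replicate 3, the same 6-library design recovered 100%. The simulation did not place libraries of the other profile within a group, so it does not model how these dilute a difference. The 0 genes therefore do not show that the lines are alike. Among 31 gene lists fixed beforehand, 12 passed the set test with its preset correlation and 0 with an estimated one. The fibroblast and extracellular matrix list was lower in the libraries labelled HEK293T (median log2 fold change -0.87, camera adjusted p = 9.96e-08, and adjusted p = 0.824 with an estimated correlation), with 0 of its 44 members past the gene test, also when adjusted over the list alone. The DNA replication and E2F target list was higher (median 0.59, adjusted p = 0.000137, and adjusted p = 0.824 with an estimated correlation), again with 0 of 41 members past the test on either adjustment. Without the library labelled HEK293T replicate 1 the lists past the preset test numbered 5, and without that labelled HEK293T replicate 2 they numbered 7.

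The comparison was then run without the 2 depleted libraries whose markers contradict their labels, which left HEK293T replicates 1 and 2 against IMR-90 replicates 2 and 3. This choice was made after the data were seen. Because markers of both lines led to it, the direction of fibroblast, contractile, fetal RNA-binding and related lists below is not independent evidence, and each direction rests on the labels of the 4 libraries kept. Of 17737 genes, 4783 were higher and 4538 lower in HEK293T, 9321 in all, and 7790 of these had an absolute log2 fold change of at least 1. The common biological coefficient of variation was 0.267. The median log2 fold change of all genes was 0.10, and with library size as the only scaling it became 0.81 and the split moved to 8083 higher and 2624 lower. All directions below are relative to TMM scaling. In these 4 libraries label and profile coincide, so an effect that follows the label cannot be told apart from the line. Cytoplasmic rRNA features, whose share followed the label in the depleted libraries, were higher here in 3 of 5 cases. Without HEK293T replicate 1 the test called 4782 genes and without HEK293T replicate 2 it called 4938.

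Matrix and contractile genes fell in HEK293T. Of 44 fibroblast and extracellular matrix genes, 42 were lower and 0 higher, with 42 lower adjusted over the list alone (camera adjusted p = 6.39e-19, and adjusted p = 0.565 with an estimated correlation). FN1 stood at 146 ± 51.7 normalised CPM in HEK293T and 11670 ± 52.4 in IMR-90 (SD, n = 2 each; log2 fold change -6.35 ± 0.42, SE, edgeR adjusted p = 6.86e-05). COL1A2 fell from 6832 ± 260 to 5.02 ± 0.059 normalised CPM (log2 fold change -10.45 ± 0.37), and VIM, an intermediate filament gene of mesenchymal cells, by 3.90 on the log2 scale. Of 20 smooth muscle and contractile genes, 19 were lower and 0 higher, with 19 adjusted over the list alone (adjusted p = 2.90e-10, and adjusted p = 0.565 with an estimated correlation), among them the actin cross-linker FLNA (-2.91), the non-muscle myosin heavy chain MYH9 (-4.06) and TAGLN (-9.99). Genes secreted by senescent fibroblasts were lower in 17 of 23 cases and higher in 1, with 18 and 2 adjusted over the list alone (adjusted p = 7.46e-06, and adjusted p = 0.634 with an estimated correlation), and 16 lower and 3 higher with library size as the only scaling. The insulin-like growth factor binding protein genes IGFBP5 (-9.69) and IGFBP3 (-9.56) were the most abundant of these, and PLAT, which encodes tissue plasminogen activator, fell by 5.06 on the log2 scale but lost its call without either HEK293T library. Lung mesenchyme transcription factors and signals were lower in 10 of 14 cases and higher in 1, with 11 and 1 adjusted over the list alone (adjusted p = 0.00215, and adjusted p = 0.768 with an estimated correlation), as for the growth factor gene FGF7 (-10.94) and TBX3 (-3.17).

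MHC class I antigen presentation genes were also mostly lower. Of 19, 13 were lower and 1 higher, the same counts as when adjusted over the list alone (adjusted p = 0.000505, and adjusted p = 0.768 with an estimated correlation). B2M, the light chain of every class I molecule, stood at 106 ± 32.5 normalised CPM in HEK293T and 762 ± 198 in IMR-90 (SD, n = 2 each; log2 fold change -2.89 ± 0.32, SE, adjusted p = 0.000569). The chaperone gene CALR fell by 1.67 on the log2 scale. HLA-F was higher (2.55 ± 0.51), a call lost without HEK293T replicate 2. HLA-F shares reads with close paralogs, so its value is uncertain.

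Most DNA replication genes tested, and some mitosis genes, were higher in HEK293T. Of 41 DNA replication and E2F target genes, 37 were higher and 0 lower, with 37 adjusted over the list alone (camera adjusted p = 1.56e-08, and adjusted p = 0.768 with an estimated correlation). The DNA polymerase alpha subunit gene POLA1 stood at 291 ± 43.1 normalised CPM against 13.2 ± 5.53 (log2 fold change 4.43 ± 0.36, SE, adjusted p = 0.000181). The ribonucleotide reductase gene RRM1 (1.83) and the sliding clamp gene PCNA (2.44) were higher as well. Of 34 mitosis genes, 13 were higher and 0 lower, with 2 higher adjusted over the list alone (adjusted p = 0.000192, and adjusted p = 0.768 with an estimated correlation). The topoisomerase gene TOP2A (2.52 ± 0.72) and the mitotic kinase gene CDK1 (3.31 ± 0.72) were among them, and both calls were lost without either HEK293T library. In IMR-90 replicates 2 and 3 TOP2A stood at 31.4 and 126.7 normalised CPM and CDK1 at 5.82 and 22.92. The size of both changes thus depends on the IMR-90 library used. Of 72 clustered replication-dependent histone genes, 50 were higher and 14 lower, with 51 and 15 adjusted over the list alone (adjusted p = 0.000577, and adjusted p = 0.768 with an estimated correlation). The linker histone gene H1-2 stood at 996 ± 193 against 72.6 ± 43.3 normalised CPM (log2 fold change 3.74 ± 0.49), H4C3 rose by 4.01 and H3C2 by 4.57 on the log2 scale, while H1-5 was lower (-7.89 ± 1.26). The calls of H3C2 and H1-5 were lost without either HEK293T library. Histone genes share near-identical coding sequence, so single members are uncertain.

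Developmental genes divided by family and cluster. Of 33 HOX genes, which set position along the body axis, 22 were higher in HEK293T and 5 lower, with 22 and 6 adjusted over the list alone (camera adjusted p = 0.000817, and adjusted p = 0.634 with an estimated correlation). Counted by cluster, a grouping made after the data were seen, 8 of 8 HOXC and 7 of 7 HOXD genes were higher, 4 of 9 HOXA genes were higher and none lower, and in HOXB 3 were higher and 5 lower of 9. HOXB9 had 1681 counts in the HEK293T libraries and 3 in the IMR-90 libraries, a ratio of 203 with a counting interval from 74.1 to 1052. HOXD4 had 1465 counts against 1, a ratio of 485 with an interval from 102 to 22410. HOXB3 lay the other way, at 2.84 ± 0.863 against 24.6 ± 5.16 normalised CPM (log2 fold change -3.15 ± 0.32, SE, adjusted p = 0.000409). Of 20 epithelial genes, 14 were higher and 1 lower, with 14 and 2 adjusted over the list alone (adjusted p = 0.00241, and adjusted p = 0.621 with an estimated correlation), as for the tight junction gene OCLN (5.69), the desmosomal gene PKP2 (4.38) and the keratin gene KRT19 (3.01). Of 11 fetal RNA-binding and let-7 pathway genes, 4 were higher and 3 lower, with 4 and 5 adjusted over the list alone (adjusted p = 0.612). LIN28B rose by 7.90 ± 0.38 on the log2 scale, and the chromatin protein gene HMGA2, a let-7 target, fell by 3.02.

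Most imprinted genes tested, and the small nucleolar RNAs (snoRNAs) embedded in 2 imprinted regions, were lower in HEK293T. Of 19 imprinted genes, 13 were lower and 4 higher, the same counts as when adjusted over the list alone (camera adjusted p = 0.00501, and adjusted p = 0.621 with an estimated correlation). The long non-coding RNA gene MEG3 stood at 0.0948 ± 0.00465 against 197 ± 16.5 normalised CPM (log2 fold change -11.01 ± 0.32, SE, adjusted p = 2.22e-05), and MEST fell by 10.26 on the log2 scale. IGF2R was lower by less (-0.94 ± 0.21), GRB10 was higher (1.62 ± 0.20), and H19 had 332 counts against 1, a ratio of 110 with a counting interval from 22.9 to 5089. The call of IGF2R was lost without either HEK293T library and with library size as the only scaling. Of 201 small nucleolar and Cajal body RNA features, 56 were lower and 12 higher, with 50 and 10 adjusted over the list alone (adjusted p = 0.00153, and adjusted p = 0.813 with an estimated correlation), and with library size as the only scaling 49 were lower and 26 higher. These numbers divided by genomic cluster, a grouping made after the data were seen. All 30 tested SNORD113 and SNORD114 features, which lie beside MEG3 on chromosome 14, and all 17 tested SNORD115 and SNORD116 features on chromosome 15 were lower, and of the other 154 features 9 were lower and 12 higher. SNORD116-8 (hg19 chromosome 15, 25315579 to 25315673) had 0 counts in the HEK293T libraries and 1240 in the IMR-90 libraries, at least 1068-fold lower against a floor of 3 counts over the group. It stood at 54.4 and 10.36 normalised CPM in IMR-90 replicates 2 and 3, so that bound rests mostly on replicate 2. SNORD114-20 had 3 counts against 1842, a ratio of 1468 with a counting interval from 542 to 7702. SNORA12, outside these clusters, was higher (2.01 ± 0.45). Calls of SNORD116-8, SNORD116-16, SNORD116-23, SNORD116-24, SNORD114-1, SNORD114-3 and SNORA12 were lost without either HEK293T library, and that of SNORD114-20 was kept.

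Among RNA:DNA hybrid processing genes, the group closest to the series title, 20 of 49 were higher in HEK293T and 5 lower, the same counts as when adjusted over the list alone, and the list did not pass the set test (camera adjusted p = 0.0706, and adjusted p = 0.768 with an estimated correlation). With library size as the only scaling 35 were higher and 2 lower. BRCA1 stood at 149 ± 6.82 against 7.96 ± 4.54 normalised CPM (log2 fold change 4.18 ± 0.44, SE, adjusted p = 0.000878), and the Fanconi anaemia gene FANCI rose by 3.33 on the log2 scale. The helicase gene DDX21 was higher by less (0.97 ± 0.27), a call lost without HEK293T replicate 2, and the nuclease gene ERCC5 was lower (-1.55 ± 0.22).

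The largest single differences under the naming rule came from genes close to absent in one line. NMU, a neuropeptide gene (ENSG00000109255, hg19 chromosome 4, 56461396 to 56502865), had 1077 counts in the HEK293T libraries and 0 in the IMR-90 libraries, at least 139-fold higher. DSC2, a desmosomal cadherin gene, had 3719 counts against 1, a ratio of 1235 with a counting interval from 258 to 56850, and MAL2, an epithelial trafficking gene, had 4020 against 2, a ratio of 704 with an interval from 215 to 6424. NEBL, CPVL, CECR2, SLAIN1 and NUP62CL completed this group, with 2053 to 2947 counts in HEK293T and 1 in IMR-90 each. In the other direction POSTN, a matrix gene, had 0 counts against 1550, at least 1335-fold lower, with 3.13 and 66.9 normalised CPM in the IMR-90 libraries and an adjusted p of 0.0404 that was lost without either HEK293T library. CHRM2, a muscarinic receptor gene, had 1 count against 5314, a ratio of 10020 with an interval from 2464 to 542500. All 64 genes named in this comparison kept their sign in every alternative run that tested them (35 were tested under the filter of 1 CPM in 3 libraries), but not all kept their calls. Of the 64, the call held for 62 with library size as the only scaling, 58 against a log2 fold change of 1, 53 without a filter, 50 without HEK293T replicate 1, 48 without HEK293T replicate 2 and 0 with all 6 libraries as labelled.

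**Figure D3:**
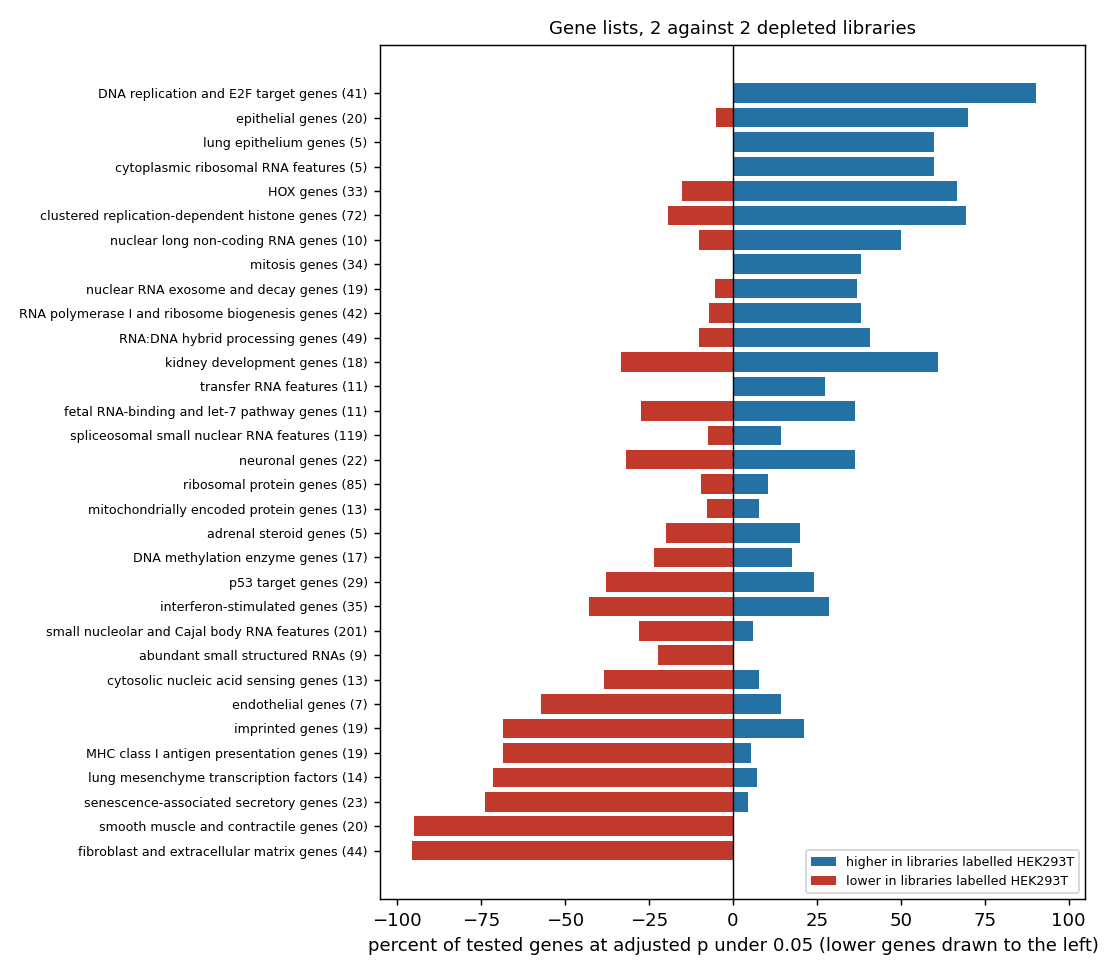
Percent of the tested members of each gene list (number tested in parentheses) that were higher, to the right, or lower, to the left, in HEK293T at an adjusted p under 0.05, from edgeR's quasi-likelihood test on the libraries labelled HEK293T replicates 1 and 2 and IMR-90 replicates 2 and 3. The fibroblast and extracellular matrix list lies farthest left, with 42 of 44 lower, and the DNA replication and E2F target list farthest right, with 37 of 41 higher. With library size as the only scaling the balance of the p53 target, interferon-stimulated and DNA methylation enzyme lists turned to higher.

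The second comparison asks what rRNA removal did to the counted RNA. Named rRNA made up 8.35% of gene counts in the library labelled IMR-90 without removal (95% Clopper-Pearson interval 8.34 to 8.37) and 8.41% in that labelled HEK293T without removal (8.38 to 8.43). In the depleted libraries it made up 0.0183% ± 0.0102 in those labelled IMR-90 and 0.108% ± 0.0362 in those labelled HEK293T (SD, n = 3 each), and the values by label did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). Cytoplasmic rRNA features made this difference, at 0.0965% ± 0.0437 in libraries labelled HEK293T and 0.00547% ± 0.00311 in those labelled IMR-90 (exact permutation p = 0.1), while mitochondrial rRNA stood at 0.0118% ± 0.00747 and 0.0128% ± 0.00709 (exact permutation p = 0.8). Features to which no gene name could be matched took 75.5% and 78.5% of gene counts in the libraries labelled IMR-90 and HEK293T without removal, and 2.21% ± 0.399 and 2.65% ± 0.314 in the depleted ones. What RNA these features hold is not given in the sources used here. Named rRNA and these features together took 83.9% and 86.9% without removal, so the named share must not be read as that of all rRNA. Protein-coding genes took 15.0% and 12.1% without removal, and 86.9% ± 4.22 and 86.3% ± 1.07 in depleted libraries.

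**Figure D4:**
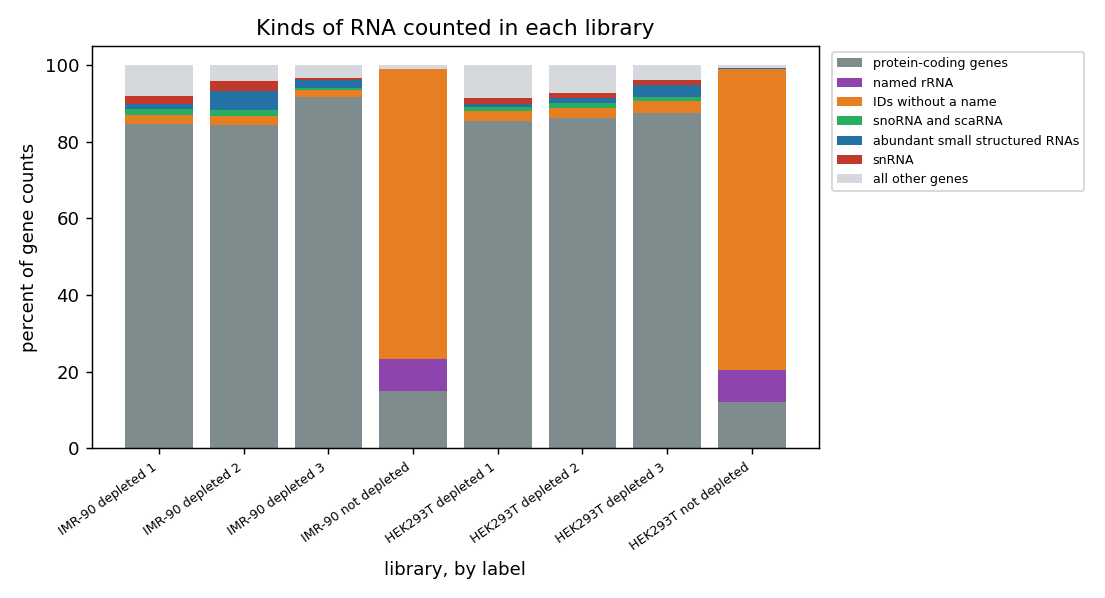
Percent of gene counts taken by each kind of RNA, stacked from 0 to 100, in each of the 8 libraries by label. Protein-coding genes take 15.0% and 12.1% in the libraries labelled IMR-90 and HEK293T without removal and from 84.3% to 91.7% in the 6 depleted libraries.

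In the fit of all 8 libraries with cell line as a covariate, mitochondrial rRNA, most mitochondrially encoded protein genes and 5.8S and 5S rRNA copies were lower with removal. Transfer RNA features did not follow as a group, with a median log2 fold change of 3.37 and, of 12 tested, 1 lower and 0 higher. The mitochondrial rRNA genes MT-RNR2 and MT-RNR1 had log2 fold changes of -11.52 and -11.18, with MT-RNR2 going from 169400 ± 1935 normalised CPM (SD, n = 2) to 59.4 ± 35.03 (SD, n = 6; edgeR adjusted p = 0.00219). Of 13 mitochondrially encoded protein genes, 12 were lower and 0 higher, with 12 adjusted over the list alone (camera adjusted p = 6.53e-25, and adjusted p = 0.127 with an estimated correlation). MT-ND4 went from 5192 ± 105.3 to 29.01 ± 7.44 normalised CPM (log2 fold change -7.51 ± 0.48, adjusted p = 0.00098), MT-ND5 fell by 7.20 and MT-CO3 by 3.78 on the log2 scale. Of 10 cytoplasmic rRNA features, 8 were lower and 0 higher, with 9 adjusted over the list alone (adjusted p = 4.84e-15, and adjusted p = 0.0415 with an estimated correlation, the only list to pass both), among them RNA5-8SP2 (-9.65 ± 1.16), RNA5-8SP5 (-7.68) and RNA5S9 (-8.24). RNA5-8SP2 lost its call without the library labelled IMR-90 replicate 3. Every call named in this comparison was lost in each line taken alone under the labels, where 0 genes passed (667 for IMR-90 and 694 for HEK293T at an unadjusted p under 0.05). In the 4 libraries that share a title stem, with the stem as a block, 38 genes passed, and of the 15 genes named only RNA5S9 did. The block of the HEK293T label sets a library without removal that has the IMR-90 profile against a depleted one of the other profile, so there removal is mixed with the difference between profiles.

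Short structured RNAs lay higher with removal as groups, with few members past the gene test. Of 207 small nucleolar and Cajal body RNA features, 2 were higher and 0 lower on either adjustment (median log2 fold change 2.27, camera adjusted p = 2.82e-11, and adjusted p = 0.593 with an estimated correlation), namely SNORD41 (4.42 ± 0.58) and SCARNA21 (2.29 ± 0.36). Spliceosomal small nuclear RNA features had a median of 1.91 with 0 of 132 past the gene test on either adjustment (adjusted p = 1.52e-09, and adjusted p = 0.593 with an estimated correlation), and ribosomal protein genes a median of 0.73 with 1 of 85 past it, RPL28, which was lower (-3.27 ± 0.46; list adjusted p = 1.89e-06, and adjusted p = 0.593 with an estimated correlation). With library size alone 94 of the small nuclear RNA features and 83 of the ribosomal protein genes were higher, and 0 lower. Marker lists of the lines passed the preset test too, lower with removal, with 0 members past the gene test: fibroblast and extracellular matrix (median -0.94, adjusted p = 1.30e-07, and adjusted p = 0.675 with an estimated correlation), contractile (-1.01, adjusted p = 6.87e-05, and 0.675) and lung mesenchyme genes (-1.27, adjusted p = 6.87e-05, and 0.593). Of the lung mesenchyme list 1 member was lower adjusted over the list alone. The senescence-associated secretory list was lower as well (-0.51, camera adjusted p = 0.0168, and 0.718), with 0 members past the gene test. So were the imprinted (-0.60, adjusted p = 0.00615, and 0.593) and fetal RNA-binding lists (-0.50, adjusted p = 0.0403, and 0.540), with 1 lower member each. As both libraries without removal carry the IMR-90 profile, this contrast also holds a difference between profiles, which bears on every value from it. In all, edgeR called 7 genes higher and 266 lower of 18492, DESeq2 420 and 670, and limma-voom 0 and 197. Besides SNORD41 and SCARNA21 the higher genes named by the rule were the WNT pathway gene NKD2 (2915 counts against 1, ratio 80.4, interval 13.1 to 2884), RN7SKP255 (2.58), TMED1 (2.03) and AKR1A1 (1.53), and limma-voom called none of these 6. The calls of TMED1 and AKR1A1 were lost when any of the 6 depleted libraries was left out. SCARNA21 lost its call without the libraries labelled HEK293T replicates 1 or 2 or IMR-90 replicates 2 or 3, RPL28 without HEK293T replicate 1 or IMR-90 replicate 2, and SNORD41 without the 3 libraries in doubt. The count fell to 161 genes without the library labelled HEK293T replicate 2, to 166 without IMR-90 replicate 3 and to 176 without IMR-90 replicate 2. The split of higher and lower genes depended on the scaling as well. With library size alone the median log2 fold change went from 0.34 to 3.39, and 12143 genes were higher and 120 lower. MT-RNR2, MT-RNR1, MT-ND4, MT-ND5 and the named rRNA copies were still lower. MT-CO3 and RPL28 are not among these, and of the 15 genes named 2 lost their call. The 3 libraries with markers against their labels sit in this fit, and without them the test called 44 higher and 370 lower genes of 20111.

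Without those 3 libraries the contrast is that of IMR-90 alone, 2 depleted libraries against 1, with HEK293T replicates 1 and 2 adding to the estimate of the spread and the lone library assumed to vary like them. MT-RNR2 (-10.78 ± 0.78), MT-RNR1 (-10.63), MT-ND4 (-7.51), MT-ND5 (-7.20), MT-ATP8 (-9.60) and RNA5-8SP2 (-10.39) were again lower. All 13 mitochondrially encoded protein genes were lower, also adjusted over the list alone (camera adjusted p = 8.01e-17, and adjusted p = 0.694 with an estimated correlation). RN7SL1, the RNA of the signal recognition particle, was higher with removal (16330 ± 7533 against 829 normalised CPM; log2 fold change 4.30 ± 0.75, adjusted p = 0.0267), as were NKD2 (5.92), IGFBP7 (3.30) and SCARNA13 (2.38). Of 85 ribosomal protein genes, 2 were higher, RPS10 (1.54) and RPSA (1.56), and RPL28 was lower (-2.61), while 43 were higher and 2 lower adjusted over the list alone, and 83 higher and 0 lower with library size alone (adjusted p = 2.25e-08, and adjusted p = 0.890 with an estimated correlation). The nuclear non-coding RNA TUG1 was lower (-1.55 ± 0.28) and turned to higher with library size alone (0.99). With library size alone the median log2 fold change of all genes went from 0.12 to 2.65 and the split to 13479 higher and 129 lower. The count was 118 without HEK293T replicate 1, 117 without HEK293T replicate 2, 1422 without IMR-90 replicate 2 and 2607 without IMR-90 replicate 3. The calls of RN7SL1, NKD2, SCARNA13, RPS10, RPSA, RPL28 and TUG1 were lost without either HEK293T library. Those of RPS10, RPSA, RPL28, SCARNA13 and TUG1 were also lost with limma-voom, which called 2 genes higher and 196 lower, and under the filter of 1 CPM in 3 libraries, as were those of NKD2 with the former and RN7SL1 with the latter.

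The third comparison asks whether removal changed genes by a different amount in each line. MT-RNR2, MT-ND4 and every other of the 19890 genes tested stayed above an adjusted p of 0.05 for the interaction of line and removal in edgeR's quasi-likelihood test, so 0 genes were called. At an unadjusted p under 0.05 there were 215, and DESeq2 and limma-voom called 0. That unadjusted number is below a share of 0.05 of the genes tested, so it is no sign of an interaction. In simulation the design recovered 0% of 16-fold changes, and the libraries with doubtful labels enter it.

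The last comparison sets the 2 libraries without removal against each other, 1 per line, and has no replicate check. COL1A2 stood at 5547 normalised CPM in the library labelled HEK293T and 4822 in that labelled IMR-90, FN1 at 14380 and 14890, and THY1 at 445 and 290, with no gap of the size seen between the depleted libraries kept above. Of 15963 genes with a ratio other than 1, 48.97% had the same sign as in the depleted comparison as labelled (95% Clopper-Pearson interval 48.2 to 49.8). Of 16152 such genes 44.1% had the same sign as in the comparison without the doubted libraries. The interval treats genes as independent trials, which they are not, and each line has 1 library here, so it tests nothing. The Pearson correlation of the log2 ratios with the labelled log2 fold changes was 0.110 and the Spearman correlation 0.0309, both across genes, which are not independent replicates. As a description of these libraries, the median log2 ratio of the fibroblast and extracellular matrix list was -0.05, at percentile 12.2 of 10000 random lists matched on expression. That of the mitosis list was -1.36, at percentile 0, and that of the MHC class I antigen presentation list 0.56, at percentile 99.9.

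The authors' deposited tables give a mean per line over its 3 depleted libraries, so each mean joins libraries of both marker profiles. For COL1A2 the authors' means were 86320 in HEK293T and 138800 in IMR-90, and 99.9% of the former came from the library labelled HEK293T replicate 3. For LIN28B they were 714 and 298, and 99.2% of the latter came from the library labelled IMR-90 replicate 1. For POLA1 they were 6778 and 3869, with 93.1% of the latter from that library.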

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

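All tests in this part were chosen after the marker profiles were seen, apart from both thinning tests, whose outcomes were set down before they were run. Reads aligned outside any gene feature, which enter no comparison, made up 31.7% of all counted reads in the library labelled HEK293T without removal and 26.2% in that labelled IMR-90 without removal, against 9.60% to 22.0% in the depleted libraries. This stood out as signal outside the main measurement above the level in the libraries with removal.

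The first pattern is that the depleted libraries labelled IMR-90 replicate 1 and HEK293T replicate 3 carry the profile of the other line. Depth was tested by thinning, after which each still correlated better with every library kept for the other line than with any kept for its own, by at least 0.244, and a mixture of both lines would need far more than the median 0.0332% (264 genes, IMR-90 replicate 1) and -0.488% (37 genes, HEK293T replicate 3) of RNA traced to the labelled line. Both libraries lay at the other line, at median positions of 0.990 and 1.05 over 874 genes, which is consistent with an exchange of the labels between them, although separate errors would look alike, and the cytoplasmic rRNA share stayed with the labels in both (0.00214% and 0.130%, against 0.112% and 0.0472% in the libraries labelled HEK293T replicates 1 and 2 and 0.00599% and 0.00829% in those labelled IMR-90 replicates 2 and 3), so an exchange after rRNA removal would have to leave that share in place. The labelled split called 0 genes, so 10 of 10 splits of the 6 libraries necessarily gave as many, and so few splits allow no share under 0.05; the highest other, 11851, points to a structure of the samples and is the grouping the markers had already shown. A difference between cultures of a line has no test of its own here, and as the whole cause it would have to bring both libraries to the other line's level over the 874 genes.

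The second pattern is that the library labelled HEK293T without removal carries the IMR-90 profile. Without removal in IMR-90, the 698 genes lower in HEK293T shifted by a median log2 value of -0.18. In the library labelled HEK293T they shifted by 3.44, so the IMR-90 value is -5.29% of that shift. These genes were chosen partly on the depleted IMR-90 libraries that serve as the IMR-90 baseline. The values thus show no rise with omission in IMR-90, and cannot test an effect of omission on HEK293T RNA alone. For low depth, the library labelled HEK293T replicate 1, thinned to the same depth, stayed at position -0.000423. That library also helped to set position 0, so this shows only that thinning by itself did not move it. The library labelled HEK293T without removal lay at 0.985, so it may have been made from IMR-90 RNA. Over 37 genes its excess above the depleted IMR-90 level was a median 4% of the gap to HEK293T, at a floor of 2.93 normalised CPM. The same value was not computed for the library labelled IMR-90 without removal. The 4% therefore cannot be assigned to RNA of the labelled line rather than to the omission of removal. A different state of HEK293T cells has no test of its own here, and as the whole cause it would have to bring the library to the IMR-90 level over the 874 genes.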

How the results depend on the processing

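The alternatives without the doubted libraries, and every alternative to the fits without them, were chosen after the data were seen, and the others before. No paired analysis was possible because the labels give no replicate numbers shared across lines, except for removal, where title stems tie 1 library without removal per line to a depleted one. The cell line comparison as labelled called 0 genes in every setting except DESeq2 (6) and the fit without both doubted libraries (9321), and each of its leave-one-out fits gave 0 to 0. The fit without them, against 0 with all 6 libraries, called 6196 under the stricter filter of 1 CPM in 3 libraries, where fewer genes were tested, 5270 against a log2 fold change of 1, and 4782 to 9966 with 1 library left out. DESeq2 shared 8801 of its calls with edgeR and limma-voom 9138. The removal comparison (273) gave 12263 with library size only, 1090 with DESeq2, 0 with the IMR-90 libraries only, 0 with the HEK293T libraries only, 38 in the 4 libraries that share a title stem with the stem as a block (fewer libraries and the block, changed at once), 414 without the 3 doubted libraries, and 161 to 208 with 1 library left out. Without the doubted libraries (414) it gave 13608 with library size only, 1818 without a filter, 249 with the stricter filter, 1002 with DESeq2, 198 with limma-voom and 117 to 2607 with 1 library left out. The interaction called 0 genes in every setting, which at this power says nothing of stability. For the lines, the common biological coefficient of variation was 0.824 with all 6 depleted libraries and 0.267 without the 2 doubted ones. The cause of the other changes was not tested.

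Of lists past the set test, 12 as labelled became 0 with an estimated correlation and 5 to 16 with 1 library left out. For removal, 12 became 1 and 11 to 16. Without the doubted libraries, 12 became 0 and 12 to 16 for the lines, and 11 became 0 and 8 to 12 for removal. The share of named rRNA moved with its definition. In the HEK293T library without removal it was 2.38% of all counted reads, 4.76% for cytoplasmic and 3.65% for mitochondrial rRNA alone, and in that of IMR-90 2.65%, 3.59% and 4.76%. In depleted HEK293T libraries it was 0.0359% of all counted reads and 0.0118% for mitochondrial rRNA alone, with means of 0.09445% to 0.129% when 1 was left out. In depleted IMR-90 libraries it was 0.00579% of all counted reads and 0.00547% for cytoplasmic rRNA alone, with 0.0133% to 0.0234%. For the libraries without removal, the same-sign share became 44.1% against the fit without doubted libraries. The Spearman correlation across genes became 0.00846 with a pseudocount of 0.1 and -0.0963 against that fit. All 64 genes named for the lines without the doubted libraries lost their call with all 6 libraries as labelled. Of the genes named, TUG1 alone changed sign, to 0.994 with library size only. Depth limits the HEK293T library without removal most, where 3 counts equal 2.93 normalised CPM.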

Other observations

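The tests on label-following features other than the thinning were chosen after the pattern was seen, as was the grouping by gene type, and all values on the cell lines come from the fit without the doubted libraries. Long intergenic and antisense non-coding genes were more often higher than lower in HEK293T, unlike protein-coding genes. Of 493 long intergenic genes tested, 197 were higher and 98 lower, and of 721 antisense genes 235 were higher and 115 lower, against 3793 higher and 3854 lower of 13571 protein-coding genes. The difference between types was not tested, antisense counts may hold reads of the opposite strand as the strand setting is not stated, and library size as the only scaling moved the split of all genes from 4783 and 4538 to 8083 and 2624. Kidney development genes divided, with 11 of 18 higher and 6 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.191), WT1 with 340 counts against 0, at least 43.9-fold higher, and the cadherin gene CDH6 lower (-11.14 ± 0.55). Neuronal genes divided likewise, with 8 of 22 higher and 7 lower (9 and 7; adjusted p = 0.747), and 10 and 3 under library size only. Of RNA polymerase I and ribosome biogenesis genes 16 of 42 were higher and 3 lower (16 and 3; adjusted p = 0.120), and of ribosomal protein genes 9 of 85 were higher and 8 lower (5 and 2; adjusted p = 0.747), with 31 and 1 and with 49 and 1 under library size only.

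Genes of stress and defence pathways went both ways within a list, as did all genes of this fit (4783 higher and 4538 lower of 17737). Of 29 p53 targets 7 were higher and 11 lower (8 and 11 adjusted over the list alone; camera adjusted p = 0.515), the ubiquitin ligase gene MDM2 higher (1.35 ± 0.23) and the cell cycle inhibitor gene CDKN1A lower (-2.62 ± 0.27). Of 35 interferon-stimulated genes 10 were higher and 15 lower (12 and 17; adjusted p = 0.356), HERC5 with 1816 counts against 2, ratio 319 and interval 97.1 to 2903, and TRIM22 (-4.06 ± 0.32) lower. With library size as the only scaling the p53 targets stood at 12 higher and 8 lower and the interferon-stimulated genes at 14 and 13. Cytosolic nucleic acid sensing genes were lower in 5 of 13 cases and higher in 1 (5 and 1; adjusted p = 0.0706). DNA methylation enzymes (3 higher and 4 lower of 17, adjusted p = 0.798), nuclear RNA decay genes (7 and 1 of 19, adjusted p = 0.426) and nuclear long non-coding RNAs (5 and 1 of 10, adjusted p = 0.386) did not pass either. With library size as the only scaling these lists stood at 3 higher and 3 lower (nucleic acid sensing), 9 and 0 (DNA methylation) and 11 and 0 (RNA decay).

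One pattern follows the labels rather than the profiles, and was found by looking through 9 gene types and all splits of the libraries. In the 6 depleted libraries 95 of 904 processed pseudogenes (10.5%) had all 3 libraries labelled HEK293T above all 3 labelled IMR-90 and 14 (1.55%) the reverse. The shares of 13612 protein-coding genes were 0.617% and 0.933%. Exchangeable libraries would give 5% each way, but here 2 profiles cross the labels, so that 5% is no benchmark. By library size only the pseudogene shares were 8.52% and 0.885%. Depth does not account for this, since after thinning the share was 9.81%, and carry-over from a library without removal could account for at most 21.7% of the counts of RNA5-8SP2, judged from MT-RNR2. A difference between the lines as their profiles give them is argued against for the cytoplasmic rRNA share, which within each profile was at least 15.7 times as high in libraries labelled HEK293T as in those labelled IMR-90. A handling or processing step shared by the libraries of a label may account for it, but an exact permutation test of 3 against 3 (p = 0.1 for that share) goes no lower and leaves this open, as are reads shared between pseudogenes and their parents, which were not tested.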
